A study of Mus musculus with 6 samples.

How the data were processed

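The series holds RNA sequencing of RAW 264.7 cells, 3 libraries whose treatment label is ASPS-A1 and 3 labelled control. Per the labels, messenger RNA was enriched with oligo(dT) beads, fragmented and reverse transcribed with random primers. The titles number the treated libraries as ASPS-A1, A2 and A3, while the treatment label is ASPS-A1 for each, and libraries were grouped by that label. The deposited table holds counts per gene symbol in whole numbers, 1 column per library, with no normalization. Per the labels the authors used fastp 0.22.0, HISAT2 2.1.0, HTSeq 0.9.1 and DESeq 1.38.3. The genome build, the annotation, the strand setting and the treatment of reads that fit several genes are not given in the sources used here.

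Totals per library ran from 19989318 to 26137127 counts. Genes were kept with filterByExpr of edgeR on the group (minimum count 10, minimum total 15), which left 11686 of 22192 genes. Counts were scaled with TMM factors and fitted with the quasi-likelihood model of edgeR 4.0.16 (estimateDisp and glmQLFit, both robust) in R 4.3.3. The test was glmQLFTest, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Log2 fold changes are ASPS-A1 minus control, and printed CPM use the TMM-scaled library sizes. The standard error is the absolute log2 fold change divided by the square root of the F statistic. The common biological coefficient of variation was 5.66%. Library measures were compared with exact permutation tests, two-sided, where 3 libraries against 3 cannot give a p under 0.1.

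On simulated data from the fitted model (10 sets), 55.3% of genes changed 1.25-fold were called, 82.4% at 1.5-fold, 85.5% at 2-fold and 99.6% at 4-fold, and 7.41% of calls were false. Each set changed only 200 of the 11686 genes, while 65.3% were called in the data. These rates therefore do not carry over to the real comparison. The counts of same-group libraries differed by more than sampling noise (chi-square per degree of freedom 4.21 to 6.80), so none is a copy of another.

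The tests, 33 gene lists and the rule for named genes were fixed before the data were examined. The rule takes the 10 largest changes in each direction among genes with an adjusted p under 0.05, at least 10 CPM in the higher group and groups that do not overlap, leaving out predicted gene models. It adds 18 pathway genes and usual readouts chosen in advance and up to 3 called members per list and direction, or the 2 most abundant where none passed. The results of 2 genes that the rule names, 1 of them among the 18, are left out and were not replaced. Lists with at least 5 tested members (26) were tested with camera of limma 3.58.1 with a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry, adjusted over lists. The 7 remaining lists hold markers of fibroblasts, epithelium, T cells, B cells, endothelium, neutrophils and dendritic cells. Counts of risen and fallen members use the adjustment over all genes, and were repeated with adjustment over the list alone.

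The alternatives were relative log expression factors, upper-quartile factors and scaling by library totals alone; DESeq2 1.42.0 and limma-voom; no filter on low counts, and at least 1 CPM in 3 libraries; a block for the library number; leaving out each library in turn; thinning to the smallest total; a fit without robust=TRUE; and glmTreat against 1.5-fold. Offsets for transcript length and GC content were added after seeing the data. They remove, per library, a lowess trend (span 0.3) of the log ratio to the gene mean on length and then on GC content. Lengths came from the GENCODE mouse annotation and were found for 96.0% of the tested genes. Exon overlap with other genes was taken from the same annotation. On simulated counts with a length trend and no other change, 5021 genes were called without and 1 with the offsets.

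The study names no batch, so groups were compared with no block. Deviations from the group mean of libraries with the same number had correlations across genes of −0.0138, 0.00709 and 0.00398, and no ASPS-A1 library correlated best with the control library of its own number. Random lists matched on transcript length, GC content and expression (10000 per list) were drawn to compare list medians. No deposited column was left out.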

Results

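Polyadenylated RNA was sequenced from RAW 264.7 cells, a mouse macrophage-like line. Cells of 3 libraries received ASPS-A1, an acidic polysaccharide purified from Acanthopanax senticosus leaves, at 200 µg/mL for 24 h, and cells of 3 libraries were labelled control. The libraries held 22179544, 19989318 and 20139633 counts with ASPS-A1 and 23113454, 24439233 and 26137127 counts in control. This difference in depth had an exact permutation p of 0.1 (two-sided, n = 3 per group), the smallest that 3 libraries against 3 can give. The count table listed 22192 genes by symbol, of which 5884 had no count in any library and 11686 were abundant enough to test. The genome build and gene positions are not given in the sources used here. Across genes, which are not independent replicates, Spearman correlations ran from 0.996 to 0.997 within groups and from 0.961 to 0.969 between groups. The first principal component held 77.5% of the variance of the 500 most variable genes.

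The comparison asks which transcripts differ between macrophages given the polysaccharide and control macrophages. Some of the largest rises among abundant genes were in transcripts for secreted inflammatory proteins. Saa3, an acute-phase protein, was 39.3-fold higher at 186 ± 5.62 CPM (normalised read counts scaled to library size, SD, n = 3) against 4.72 ± 0.407 in control. Csf3, the growth factor for granulocytes, was 22.8-fold higher, Il1b, the precursor of interleukin-1β, was 15.2-fold higher, and the iron-sequestering lipocalin Lcn2 rose 10.4-fold to 1899 ± 17.5 CPM. Among the largest falls, Bmf, a pro-apoptotic member of the Bcl-2 family, was 14.1-fold lower and Hk2, a hexokinase of the entry step of glycolysis, was 5.10-fold lower. Of the 11686 genes tested, 3783 were higher and 3852 lower with ASPS-A1 at an adjusted p under 0.05 (edgeR), and 4051 were not past that threshold.

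The changes were widespread but mostly small. Among the genes called, the median absolute log2 fold change was 0.51, and 4443 of the 7635 changed by less than 1.5-fold. At 2-fold or more, 431 genes were higher and 671 lower. The 3 libraries of each group did not overlap for 68.5% of the genes tested, where chance gives 10%. With scaling by library totals alone, all log2 fold changes, and with them the list medians, shifted by about −0.20, and 2529 genes were then higher and 5453 lower.

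The 10 largest rises among abundant genes also included Ms4a6d (log2 fold change 3.70), the milk casein Csn1s1 (3.56), Urah (3.49), the cystathionine lyase Cth (3.27), the protease inhibitor Slpi (3.25) and the fatty acid carrier Fabp4 (3.10). Cth, which makes cysteine from cystathionine, reached 126 ± 4.42 CPM against 13.1 ± 1.37. The 10 largest falls also included the fractalkine receptor Cx3cr1 (−2.69), Fam222b (−2.68), Ankrd37 (−2.59), Tbc1d8 (−2.58), Adamtsl4 (−2.57), Mxd4 (−2.53), Kank3 (−2.27) and Rnf144b (−2.21). The strand setting of the counting is not given, so genes that share exon sequence with a neighbour are less certain. That share was 12.4% of the exon length for Urah, 26.4% for Ankrd37, 8.02% for Tbc1d8 and 6.06% for Mxd4.

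Toll-like receptor, MAP kinase and NF-κB genes moved in both directions. The series title names these themes, so their counts follow the study's own choice and are not independent evidence of a direction. Of 24 Toll-like receptors and adaptors, 10 rose, 12 fell and 2 were not past the threshold, and with scaling by library totals alone 5 rose. The co-receptor Cd14 rose from 82.6 to 143 CPM and the adaptor Myd88 by 0.50 on the log2 scale, with 11.3% of the Myd88 exon length shared with Acaa1a. Tlr4, the lipopolysaccharide receptor, was 2.11-fold lower (log2 fold change −1.08 ± 0.20 SE, adjusted p = 5.02e-06), Tlr2 had a log2 fold change of −0.42, and Tlr13 was 6.23-fold lower. The list's median log2 fold change was −0.16 (camera adjusted p = 0.598, and adjusted p = 0.703 with an estimated correlation).

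Of 36 genes of the MAP kinase cascade, 7 rose, 16 fell and 13 were not past the threshold. With scaling by library totals alone 3 rose, and with offsets for transcript length and GC content, chosen after seeing the data, 11 rose and 10 fell. Mapk3 had a log2 fold change of 0.33, Mapk14, which encodes p38α, had −0.43, and Map3k1 fell from 82.9 to 26.9 CPM. Mapk8, which encodes a JNK, had −0.087 (adjusted p = 0.234), against −0.28 (adjusted p = 0.000215) with scaling by library totals. The median was −0.065 (camera adjusted p = 0.137, and adjusted p = 0.363 with an estimated correlation), against −0.12 without ASPS-A1 replicate 1 or 3 and −0.14 without control replicate 3. Of 15 AP-1 and early growth response factors, 8 rose, 5 fell and 2 were not past the threshold, and 5 rose with scaling by library totals alone. Fos rose 2.60-fold, Jun (0.79) and Batf (1.80) also rose, and Junb fell (−0.61). The median was 0.29 (camera adjusted p = 0.137, and adjusted p = 0.363 with an estimated correlation). Of 12 dual-specificity phosphatases, which switch off MAP kinases, 3 rose, 6 fell and 3 were not past the threshold, with Dusp1 at 1.55 and Dusp14 at −0.74. Their median was −0.21 (camera adjusted p = 0.481, and adjusted p = 0.547 with an estimated correlation).

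Of 29 NF-κB subunits, inhibitors and kinases, 15 rose, 7 fell and 7 were not past the threshold. The inhibitor Nfkbia, itself an NF-κB target, rose 1.81-fold to 333 ± 14.9 CPM. Traf1 (1.70), Bcl3 (1.19), Ikbke (1.10) and Nfkb1 (0.44) rose, the kinase subunit Ikbkg fell (−0.45), and Rela had a log2 fold change of 0.052 (adjusted p = 0.669). The list was higher against other genes (median 0.18, camera adjusted p = 0.0352, but adjusted p = 0.363 with an estimated correlation). That call ended with limma-voom (adjusted p = 0.0739) and with scaling by library totals (adjusted p = 0.0735), where the median was −0.012 and 11 members fell. Adjusted over the list alone, the counts of these 5 lists were the same.

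**Figure D1:**
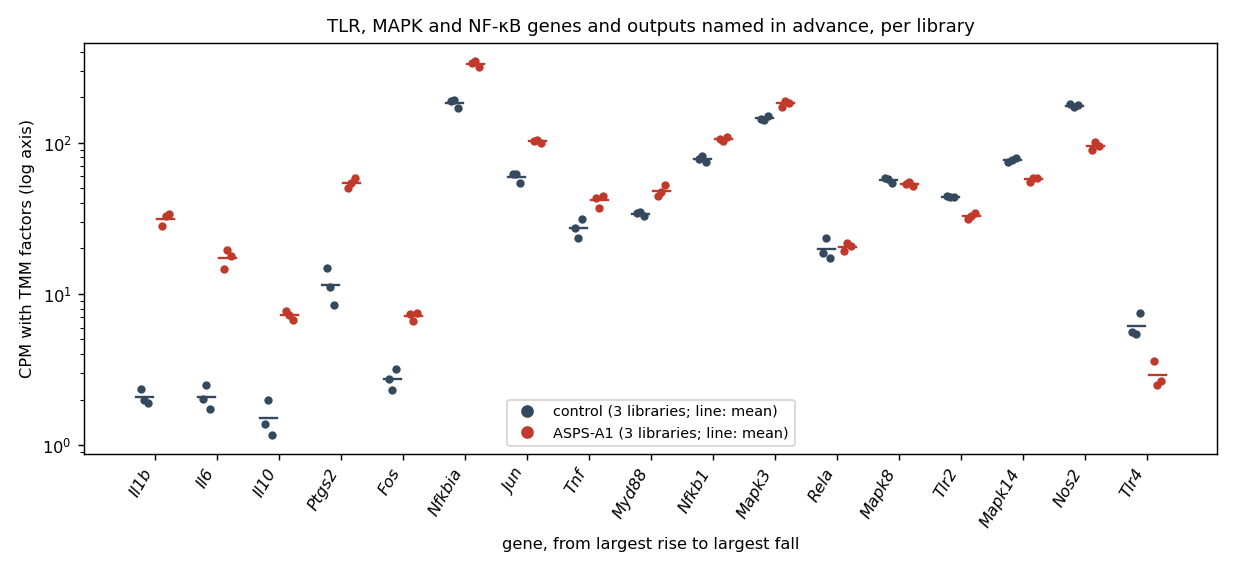
Normalised read counts (CPM), on a log axis, of 17 genes named in advance in each of the 3 ASPS-A1 and 3 control libraries. Points are libraries and lines are group means, ordered from the largest rise (Il1b, log2 fold change 3.92) to the largest fall (Tlr4, −1.08).

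Cytokine, chemokine and inflammatory effector genes rose together. Of 20 inflammatory cytokines, 17 rose, 0 fell and 3 were not past the threshold. Il6 was 8.32-fold higher at 17.4 ± 2.58 against 2.09 ± 0.395 CPM, and the anti-inflammatory cytokine Il10 was 4.81-fold higher. The interleukin-1 receptor antagonist Il1rn was 47.5-fold higher, from 14 counts over the control libraries to 505 with ASPS-A1, while Tnf rose 1.52-fold (41.6 ± 3.74 against 27.4 ± 3.90 CPM, adjusted p = 1.87e-07). The median was 1.70 (camera adjusted p = 3.80e-12, and adjusted p = 0.101 with an estimated correlation). A count of 1 fallen cytokine was reached without ASPS-A1 replicate 1, without control replicate 1, or with the length and GC offsets. Of 13 chemokines, 11 rose and 2 fell, or 1 fell without ASPS-A1 replicate 3 or without control replicate 2. The monocyte attractant Ccl2 rose 7.63-fold to 92.6 ± 5.86 CPM, Ccl7 rose from 0.433 to 9.20 CPM, the neutrophil attractant Cxcl2 rose 6.59-fold, and the eosinophil attractant Ccl24 fell 3.02-fold. The median was 2.06 (camera adjusted p = 1.06e-15, and adjusted p = 0.101 with an estimated correlation).

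Of 32 inflammatory effector enzymes and proteins, 23 rose, 6 fell and 3 were not past the threshold. Besides Saa3, Lcn2 and Slpi, the inducible cyclooxygenase Ptgs2 rose 4.75-fold (54.4 ± 4.22 against 11.5 ± 3.27 CPM). Nos2, the inducible nitric oxide synthase, fell 1.85-fold, to 95.4 ± 5.67 CPM (log2 fold change −0.89 ± 0.05 SE, adjusted p = 1.15e-19), and the inflammasome sensor Nlrp3 also fell (−0.71). The median was 0.82 (camera adjusted p = 1.20e-14, and adjusted p = 0.101 with an estimated correlation). Of 24 feedback regulators of cytokine and Toll-like receptor signalling, 11 rose, 8 fell and 5 were not past the threshold. The cytokine signalling inhibitor Cish (−1.75), the peptidoglycan sensor Nod2 (−1.45) and Trib1 (−2.35) fell, while Nfkbia, Il10 and Il1rn rose. Their median was 0.14, or −0.056 with scaling by library totals and 0.050 without control replicate 3 (camera adjusted p = 0.397, and adjusted p = 0.547 with an estimated correlation). The counts of these 4 lists were the same when adjusted over the list alone.

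Phagocytic, scavenger and lectin receptors were mostly higher, with 17 of 29 risen, 8 fallen and 4 not past the threshold. The scavenger receptor Msr1 rose 5.15-fold to 130 ± 12.4 CPM and the lectin Clec4d rose 3.11-fold. The inhibitory Fc receptor Fcgr2b rose (1.71) while its paralog Fcgr3 fell (−1.48), as did the complement receptor C5ar1 (−0.85). How reads shared between paralogs were assigned is not given. The median was 0.44 (camera adjusted p = 0.000525, and adjusted p = 0.108 with an estimated correlation). Of 27 antigen presentation and co-stimulation genes, 14 rose, 9 fell and 4 were not past the threshold, and 9 rose with scaling by library totals or with the length and GC offsets. The co-stimulatory receptor Cd40 rose 2.44-fold and Cd274, which encodes PD-L1 and shares 14.1% of its exon length, rose 2.62-fold. The class II gene H2-Eb1 (−0.76), Icosl (−0.53) and the peptide transporter Tap1 (−0.43) fell. The median was 0.14 (camera adjusted p = 0.349, and adjusted p = 0.547 with an estimated correlation), and it was −0.057 with scaling by library totals and −0.034 with the offsets.

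Interferon-stimulated genes moved both ways, with 11 of 36 risen, 14 fallen and 11 not past the threshold. Isg15 had a log2 fold change of 1.79 from 30 counts over the control libraries to 77, whereas Epsti1 (−0.90) and Usp18 (−0.71) fell. The median was −0.19 while the mean was 0.21 (camera direction higher, adjusted p = 0.770, and adjusted p = 0.859 with an estimated correlation). The number fallen was 9 without control replicate 3 and 9 with DESeq2. Of 11 alternative-activation genes, 3 rose, 2 fell and 6 were not past the threshold. Flt1 (3.02), Ccl22 (2.23) and Myc (2.16) rose, and Egr2 fell from 105 to 11 counts. Their median was 0.45 (camera adjusted p = 0.310, and adjusted p = 0.490 with an estimated correlation), or −0.027 without ASPS-A1 replicate 1, 0.26 without ASPS-A1 replicate 2 and 0.19 without control replicate 3. The number fallen was 4 without control replicate 1 or with scaling by library totals, and 1 with a filter of at least 1 CPM in 3 libraries. Adjusted over the list alone, 9 phagocytic receptors, 10 antigen presentation genes and 15 interferon-stimulated genes fell and 12 interferon-stimulated genes rose, and the other counts were the same.

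**Figure D2:**
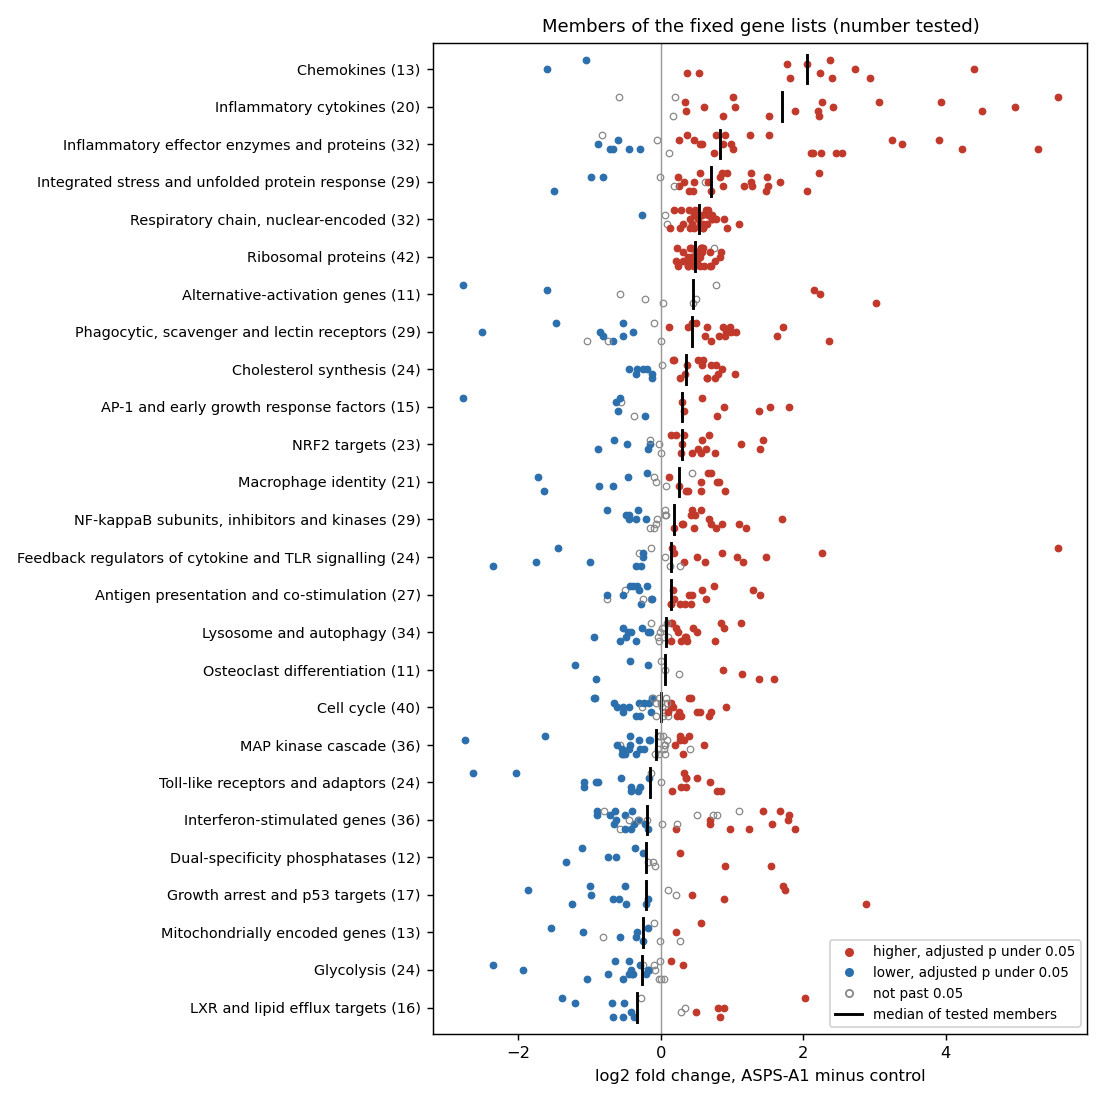
Log2 fold change (ASPS-A1 minus control) of each tested member of the 26 gene lists with at least 5 tested members. Filled points have an adjusted p under 0.05, open points do not, and black lines are list medians, such as 2.06 for chemokines and −0.27 for glycolysis.

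The glycolysis list mostly fell, and it also holds genes outside glycolysis itself, such as Bnip3. Of its 24 genes, 15 fell, 2 rose and 7 were not past the threshold. Hk2 fell from 119 ± 8.41 to 23.4 ± 1.88 CPM, the lactate exporter Slc16a3 fell 2.05-fold, and the mitophagy receptor Bnip3, with 22.3% of its exon length shared, fell 3.82-fold. Tpi1 rose (0.32), with 0.082 (adjusted p = 0.0650) under the length and GC offsets. Slc16a1 had 0.14, which lost the call without control replicate 1 (0.12, adjusted p = 0.0548), leaving 1 risen member, and turned to −0.057 with scaling by library totals. The median was −0.27 (camera adjusted p = 2.68e-06, and adjusted p = 0.175 with an estimated correlation). Cholesterol synthesis genes were mostly higher, with 16 of 24 risen, 7 fallen and 1 not past the threshold. Fdps (1.04, with 26.7% of its exon length shared), Nsdhl (0.86) and Mvk (0.81) rose, while Stard4 (−0.45) and Insig1 (−0.34), which holds back sterol synthesis, fell. The number fallen was 4 without ASPS-A1 replicate 3, without control replicate 2, or with the length and GC offsets. The median was 0.35 (camera adjusted p = 0.0123, or 0.0708 with scaling by library totals, and adjusted p = 0.547 with an estimated correlation). Of 16 LXR and lipid efflux targets, 5 rose, 8 fell and 3 were not past the threshold. The lipoprotein lipase Lpl (0.89) and the lipid droplet coat protein Plin2 (0.82) rose and the desaturase Scd2 (−0.69) and Mylip (−1.21) fell. Their median was −0.33 (camera adjusted p = 0.598, and adjusted p = 0.657 with an estimated correlation), against −0.15 without ASPS-A1 replicate 3, −0.20 without control replicate 1 and −0.14 with the offsets. These 3 lists had the same counts adjusted over the list alone.

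Stress response genes rose, with 23 of 29 integrated stress and unfolded protein response genes risen, 3 fallen and 3 not past the threshold. Ddit3, which encodes the transcription factor CHOP, rose 4.66-fold to 281 ± 13.4 CPM, Ppp1r15a rose 4.13-fold and Trib3 rose 3.17-fold. Ddit4 (−1.50), Sesn2 (−0.99) and Xbp1 (−0.81) fell. The median was 0.70 (camera adjusted p = 1.20e-14, and adjusted p = 0.101 with an estimated correlation). Of 23 NRF2 targets, 15 rose, 5 fell and 3 were not past the threshold, and 8 fell with scaling by library totals. The ferritin heavy chain Fth1, which has pseudogene copies, rose 2.69-fold to 8387 ± 285 CPM and the cystine transporter Slc7a11 rose 2.62-fold. Gclc, the catalytic subunit for glutathione synthesis, fell (−0.88), as did Nfe2l2, which encodes NRF2 itself (−0.47). The median was 0.29 (camera adjusted p = 0.00116, and adjusted p = 0.363 with an estimated correlation). Of 34 lysosome and autophagy genes, 15 rose, 10 fell and 9 were not past the threshold, against 9 risen and 17 fallen with scaling by library totals. The cathepsins Ctsl (0.89, with 26.8% of its exon length shared) and Ctsz (0.85) rose and Gpnmb (−0.94) and Mitf (−0.57) fell. Their median was 0.068, or −0.13 with scaling by library totals (camera adjusted p = 0.348, and adjusted p = 0.547 with an estimated correlation). Adjusted over the list alone, 24 stress response genes rose, and the other counts of these 3 lists were the same.

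Ribosomal protein and respiratory chain genes were higher, and fold changes tended to be lower for genes with longer transcripts. Of 42 ribosomal protein genes, 41 rose, 0 fell and 1 was not past the threshold (median 0.49), with Rplp1 at 0.83 and Rps20 at 0.76. Camera gave an adjusted p of 1.30e-10, with adjusted p = 0.490 with an estimated correlation. All genes with a ribosomal protein name, a wider set than these 42, held 12.9% ± 0.546 of all counts with ASPS-A1 against 10.6% ± 0.409 in control (SD, n = 3, exact permutation p = 0.1). Of 32 nuclear-encoded respiratory chain genes, 29 rose, 1 fell and 2 were not past the threshold (median 0.53, camera adjusted p = 1.36e-08, and adjusted p = 0.444 with an estimated correlation). Cytochrome c (Cycs, 0.93) and Uqcrq (1.09) rose, Sdha fell (−0.26), and 3 fell with scaling by library totals. Adjusted over the list alone, 42 ribosomal protein genes rose, and the respiratory chain counts were the same.

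Across the 11215 genes with a known transcript length, log2 fold change and length had a Spearman correlation of −0.385, where genes are not independent replicates. The median log2 fold change was 0.48 in the shortest of 10 equal bins of transcript length (195 to 1279 nt) and −0.27 in the longest (6663 to 106824 nt). With offsets for length and GC content, 20 ribosomal protein genes rose and 2 fell (median 0.089, camera adjusted p = 0.176), and 21 respiratory chain genes rose and 4 fell (median 0.15, adjusted p = 0.0434). Of 13 mitochondrially encoded genes, 2 rose, 7 fell and 4 were not past the threshold, with the same counts adjusted over the list alone. ND3 (−1.54) and ND5 (−0.57) fell, ND4 (0.57) rose, and COX1 had 0.21, or 0.018 (adjusted p = 0.691) with scaling by library totals and −0.12 (adjusted p = 0.00517) with the offsets. Their median was −0.25 (camera adjusted p = 0.137, and adjusted p = 0.635 with an estimated correlation). This list passed the threshold without control replicate 1 (adjusted p = 0.00311) and with the offsets (median −0.75, adjusted p = 4.27e-08, 1 risen and 12 fallen), and 1 rose with scaling by library totals.

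**Figure D3:**
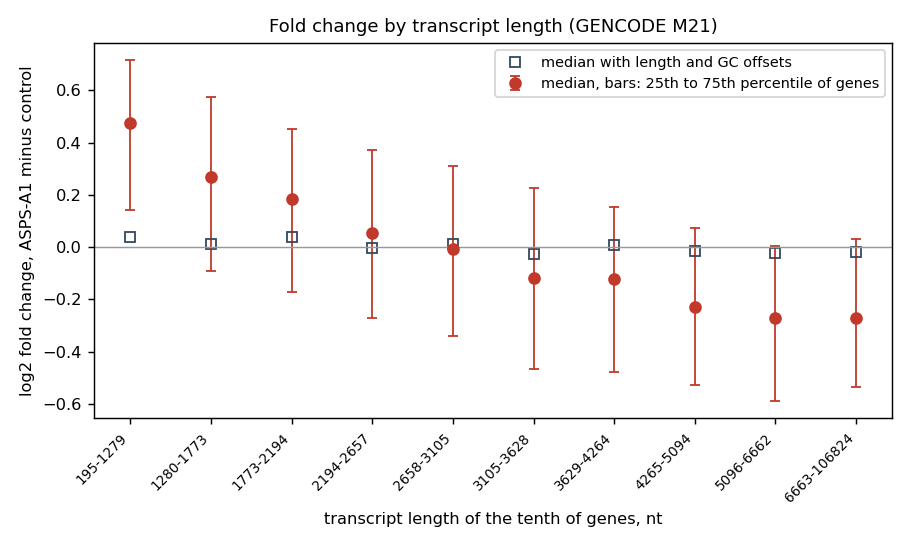
Median log2 fold change (ASPS-A1 minus control) in each of 10 equal bins of the tested genes by transcript length, with bars from the 25th to the 75th percentile and squares for the median after offsets for length and GC content. Medians ran from 0.48 in the shortest bin to −0.27 in the longest.

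Proliferation genes moved in both directions. Of 40 cell cycle genes, 14 rose, 14 fell and 12 were not past the threshold, with Tyms (0.92) and Pcna (0.71) of DNA synthesis higher and Cenpf (−0.93), Kif23 (−0.66) of mitosis and the cyclin Ccnd2 (−0.92) lower. The median was 0.0067 and the mean −0.024 (camera direction lower, adjusted p = 0.598, and adjusted p = 0.859 with an estimated correlation). The median was −0.19 with scaling by library totals (7 risen, 24 fallen), −0.045 with upper-quartile factors (9 risen), −0.0019 with no filter, 0.063 with the offsets (19 risen, 13 fallen), and from −0.010 (without control replicate 2) to 0.026 (without ASPS-A1 replicate 3) when each library was left out. Of 17 growth arrest and p53 targets, 5 rose, 10 fell and 2 were not past the threshold. Gadd45g (2.88), Gadd45a (1.75, with 19.1% of its exon length shared) and Gadd45b (1.72) rose and Btg2 (−1.86) and Trp53inp1 (−1.25) fell. The median was −0.21 and the mean 0.014 (camera direction lower, adjusted p = 0.796, and adjusted p = 0.859 with an estimated correlation). Of 11 osteoclast differentiation genes, 4 rose, 4 fell and 3 were not past the threshold, or 2 fell without ASPS-A1 replicate 2. The acid phosphatase Acp5 (1.59) rose and Nfatc1, the main transcription factor of that fate, fell (−1.21). Their median was 0.064, or −0.13 with scaling by library totals (camera adjusted p = 0.486, and adjusted p = 0.547 with an estimated correlation). That median was 0.026 and 0.030 without ASPS-A1 replicate 2 and 3, 0.038 without control replicate 2, and 0.10 without ASPS-A1 replicate 1 or control replicate 1. Of 21 macrophage identity genes, 11 rose, 6 fell and 4 were not past the threshold (median 0.26, camera adjusted p = 0.191, and adjusted p = 0.547 with an estimated correlation). The Fc receptor chain Fcer1g rose (0.90), and Cd33 (−1.72) and the pore-forming protein Mpeg1 (−0.86) fell. Adjusted over the list alone, 15 cell cycle genes fell, and the other counts of these 4 lists were the same.

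Markers of other cell types were few. Of the epithelial markers 0 were abundant enough to test. The fibroblast list had 1 tested gene, Acta2, at 0.80 (adjusted p = 0.0757), and of 3 tested B cell markers 0 passed, with Cd79b at 34.6 ± 3.29 against 31.0 ± 1.23 CPM (adjusted p = 0.0792, or 0.030 without ASPS-A1 replicate 1). The T cell list had 1 tested gene, Lck, which rose (1.22), both of 2 tested endothelial markers rose (Eng, 0.98, and Pecam1, 0.80), and of 2 tested neutrophil markers Csf3r rose (0.63). Of 3 tested dendritic cell markers 1 rose, Fscn1, from 10 to 48 counts. These lists were too short for a camera test, and their counts were the same when adjusted over the list alone.

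Of the 26 lists with a camera test, 10 were higher and 1 lower with the preset correlation. With an estimated correlation 0 passed (smallest adjusted p 0.101, with 6 at an unadjusted p under 0.05). Other divisions of the 6 libraries into 3 and 3 gave 3 to 8 lists with the preset correlation. Each of them mixes ASPS-A1 and control libraries and keeps part of the difference between the groups, so these counts are not a rate of false calls. The labels do not say whether the libraries of a group came from separate cultures, nor whether A1, A2 and A3 in the treated titles number replicates or fractions, so SDs and p-values measure only the spread between these libraries.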

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

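For named genes, 3032 comparisons with an alternative were counted as the same, 83 lost the call, 2 gained it and 2 reversed. Most of the lost calls were with glmTreat against 1.5-fold, which asks a stricter question than the other alternatives. Reversals were counted only for genes past the threshold in the edgeR fit with TMM factors. A change of direction in the other named genes was counted as the same. Counts of risen and fallen members stayed within 1.5 times in 857 comparisons and moved further in 79. Without 1 library, 3511 to 3679 genes were higher and 3597 to 3707 lower. The block for the library number gave 3746 and 3807, with the paired libraries correlated at −0.0138, 0.00709 and 0.00398, and 7524 of the 7635 calls were kept.

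With scaling by library totals, 261 genes were higher and 1060 lower at 2-fold or more, Slc16a1 turned to −0.057, and the list tests gave 0.0735 for NF-κB and 0.0708 for cholesterol synthesis. All fold changes shift by about −0.20 under this scaling, and the cause of the changed list tests was not tested. Limma-voom gave 0.0739 for NF-κB, and the cause was not tested. By its stricter question, glmTreat against 1.5-fold left 812 higher and 880 lower. The offsets for length and GC content, chosen after seeing the data, kept 6033 calls and reversed 86. They turned COX1 to −0.12 and gave list tests of 0.176 for ribosomal proteins and 4.27e-08 for mitochondrially encoded genes. Without 1 library, the latter list ran from 0.00311 (without control replicate 1) to 0.210, and the cause was not tested.

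With an estimated correlation 0 lists passed. For phagocytic receptors the estimate was 0.0117, near the preset 0.01, and the adjusted p still went from 0.000525 to 0.108. A higher correlation between the genes therefore does not explain the lost call of that list. The cause was not tested further. The adjusted p was 0.101 for cytokines, chemokines, effectors and the stress response, 0.108 for phagocytic receptors, 0.175 for glycolysis, 0.363 for NF-κB and NRF2 targets, 0.444 for the respiratory chain, 0.490 for ribosomal proteins and 0.547 for cholesterol synthesis. Fry, which does not compare a list with other genes, passed 22 lists. It added the MAP kinase cascade (5.21e-05), AP-1 factors (0.000411), dual-specificity phosphatases (0.00941), alternative activation and antigen presentation (both 0.00196), feedback regulators (0.00127), LXR targets (0.00768), lysosome (0.000948), osteoclast (0.00384), macrophage identity (0.00319) and mitochondrially encoded genes (0.0277). With the offsets, list medians became −0.018 for the MAP kinase cascade, 0.18 for AP-1 factors, 0.19 for alternative activation, 0.27 for feedback regulators, 0.14 for osteoclast genes and 0.11 for macrophage identity. The alternative-activation median was 0.030 with limma-voom and 0.024 with at least 1 CPM. Thinning to the smallest total gave 7556 calls against 7635, and lower depths were not tested.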

Other observations

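The lists in this part were chosen after the fold changes had been seen, so their directions are not independent of these data. Genes of protein production and turnover were higher with ASPS-A1. Of 20 cytosolic tRNA synthetases, which charge tRNA with amino acids, 18 rose and 0 fell (median log2 fold change 0.75, camera adjusted p = 8.07e-16, and adjusted p = 0.104 with an estimated correlation), with Nars at 1.32 and Rars at 1.12. Of 31 proteasome subunits 30 rose and 1 fell, Psmd7 (−0.14), with a median of 0.62 and Psmc2 at 1.18 (camera adjusted p = 1.57e-16, and adjusted p = 0.104 with an estimated correlation). With the offsets for length and GC content, 18 synthetases rose (18 of the 20 have a known length), and 29 proteasome subunits rose with a median of 0.32. Before the offsets, random lists matched to the proteasome had a median of 0.43, and its own 0.62 lay at percentile 99.75 of them. All 37 mitochondrial ribosomal protein genes rose (median 0.59, camera adjusted p = 2.78e-11, and adjusted p = 0.104 with an estimated correlation), against 26 risen and 3 fallen with the offsets.

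Of 32 histone methylation and chromatin regulators, 1 rose and 21 fell, with Kmt2d at −0.62 (median −0.33, camera adjusted p = 0.000201, and adjusted p = 0.104 with an estimated correlation). With the offsets 8 rose and 12 fell and the median was −0.054. Of 8 metallothionein and metal handling genes, 3 rose and 4 fell (median −0.29, camera direction higher, adjusted p = 0.526, and adjusted p = 0.548 with an estimated correlation). The metal-binding Mt2 was at 2.01, while Trf, which encodes transferrin, was at −2.05 and the iron exporter Slc40a1 at −1.62.

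Tests of other cell type markers were chosen only after their result was seen, and all other tests below were written down before their results. In the first pattern, ribosomal protein and respiratory chain genes rose with ASPS-A1. Whether the lower number of counts in the ASPS-A1 libraries is the cause cannot be told by thinning. Thinning all libraries to the smallest total left 0.998 of the ribosomal median and 0.988 of the respiratory chain median. It also hardly moved the number of calls (7556 against 7635). Thinning takes counts from all genes of a library in proportion, so it could hardly move these medians whatever the cause. Depth differed between the groups without overlap, so whatever made it differ cannot be told apart from the treatment. A transcript length and GC bias stays open, since these medians lay at percentiles 22.5 and 82.8 of random lists matched on length, GC content and expression. The ribosomal median of 0.49 lay within the 0.40 to 0.66 of its matched lists, and with the offsets it was 0.089 and the call ended, as these short genes follow the trend that the offsets remove. Single libraries also differed from their own group in that trend, with ASPS-A1 replicate 2 at −0.247 and replicates 1 and 3 at 0.147 and 0.130, against −0.0455, −0.0573 and 0.0979 in control, so library preparation may contribute, and a change of translation genes in the cells stays a hypothesis.

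The second pattern is the rise of cytokine, chemokine and inflammatory effector genes. A transcript length and GC bias is argued against, as the smallest percentile of these 3 lists among matched random lists was 100, with medians of 1.22, 1.74 and 0.73 after the offsets. A single aberrant library is argued against by a smallest ratio of 0.926 of a list's median without 1 library to that with all. Cells of another type cannot be told apart by the markers, since at most 3 per type were abundant enough to test (largest count higher 2, Pecam1 and Eng). Some markers singled out after their values were seen had few counts over the ASPS-A1 libraries (S100a9 and Cd3e 0, Cdh5 4, Col1a1 12). Others had more (Csf3r 1813, Lck 313), so these counts do not decide it. A response of the macrophages to the polysaccharide is a candidate explanation, and endotoxin carried with the preparation, for which the labels give no measurement, was not tested and stays open.

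The third pattern is a fall of target genes of hypoxia-inducible factors and FoxO, seen first in Hk2, Bnip3 and Bmf, which were left out of the lists tested. Of 19 hypoxia-inducible factor targets 5 rose and 13 fell (median −0.30, or −0.50 with scaling by library totals and −0.49 with the offsets, camera adjusted p = 3.43e-05, and adjusted p = 0.104 with an estimated correlation), with Ero1a at −1.30 and Adm at −1.22, and of 18 FoxO targets 3 rose and 14 fell (median −0.82, camera adjusted p = 1.18e-05, and adjusted p = 0.133 with an estimated correlation), with Fbxo32 at −2.06. The fall in these genes remained when the trend with transcript length and GC content was removed with the offsets. After the offsets the medians were −0.49 and −0.70, with 11 and 14 members lower. The percentiles among matched random lists were 0.47 (over the 18 members with a known length) and 0. Both lists were chosen after the fold changes had been seen, so neither these percentiles nor the medians after the offsets can argue against a bias. A difference in medium or culture cannot be told apart from the polysaccharide. The labels used here name no culture batch or medium (0 entries), so the groups cannot be compared within one. A lower activity of these factors in cells given ASPS-A1 may explain the fall, and it was not measured.

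The 6 libraries make 10 divisions into 3 and 3, too few for a share under 0.05. Only the real division gave as many genes (1 of 10), with 7635 genes in edgeR against 0 in the highest other division, where 35 to 83 genes had an unadjusted p under 0.05 and limma-voom called 0. For gene lists tested with the preset correlation the real division gave 11 (1 of 10) and the highest other 8. Every other division mixes ASPS-A1 and control libraries. The difference between the groups then adds to the spread within each side, which lowers the number of genes called, and part of it stays in the contrast. The counts of the other divisions therefore do not measure false calls.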
